A study of Mus musculus with 4 samples.

How the data were processed

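Whole-heart RNA was measured on single-channel Illumina mouse expression bead arrays. Per the labels, 30 mg of tissue was extracted with a phenol-based reagent, RNA of 8 animals was pooled in equal amounts for each of the 4 groups, and labelled cRNA was stained with a Cy3-coupled streptavidin. Groups were taken from each sample's title, source and treatment characteristic. The treatment protocol text names vehicle for all 4 samples, including those whose other labels say DOC/salt, and was not used for grouping.

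The value table deposited by the authors holds linear bead intensities with the background left in and no visible normalization between arrays: minima lay between 71.3 and 77.8 and medians between 91.5 and 102.7. Partek is named in the submitters' processing notes with no version, and further steps are not given in the sources used here. A second table with 4 columns was not used, because its column names match no sample label. The comparisons, gene lists and rule for named genes were fixed before the data were examined, and had assumed that table, with detection p-values. Its stated fallback was therefore used, and detection was estimated from the deposited intensities.

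Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 were unnamed here. Of the named probes, 23962 matched the gene table of assembly GRCm38.p6 by gene identifier, which was used for names only, and 0 symbols changed. The build behind the probes is not given, so no coordinates are printed.

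Background was corrected with normexp by maximum likelihood and an offset of 16, followed by quantile normalization and log2, in limma 3.58.1 under R 4.3.3. A probe counted as detected on an array where under 0.01 of 1339 probes of odorant, vomeronasal and taste receptor genes were at least as bright; these genes are not expected in heart. That limit lay at intensities of 108.6, 113.5, 119.4 and 121.6 on the WT vehicle, WT DOC/salt, CM-MRKO vehicle and CM-MRKO DOC/salt arrays, and 29.4% to 34.2% of probes passed. The detection rule was set after the files were seen. Each of 16593 genes was represented by its probe with the highest mean over the 4 arrays, and a comparison used the genes detected on at least 1 of its arrays.

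Log2 differences were counted at 1.5-fold in each direction. For a gene detected on 1 array of a pair the deposited intensities are given in place of a fold, since its ratio depends on the background correction. Such genes enter the counts and list medians with their normalized values. Some list medians are also given with these genes at a bound, in which the undetected side is the higher of its own value and the lowest normalized value among detected probes of that array; this bound too is taken after background correction. The technical spread is the SD, over genes, of the difference between the log2 differences of the 2 brightest detected probes, divided by the square root of 2; it holds no spread between animals. The number of arrays, 4, limits the precision. For 41 gene lists, the median over measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list stood apart in the lowest or highest 2.5%. Lists with fewer than 3 measured members were given no percentile. Of 164 list medians, 32 stood apart, where 8.20 would for genes drawn at random. Members of a real list can move together between single pools, and the comparisons reuse the same 4 arrays. The excess over 8.20 is therefore no evidence from replicates. An additive model of treatment and genotype was fitted to all 4 arrays with lmFit and eBayes, with Benjamini-Hochberg adjustment.

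Named genes followed a rule: the 10 largest differences per direction among genes detected on every array of a comparison, without clone or predicted names; up to 3 genes per direction detected on 1 array of a pair; up to 4 members of each described list; the 10 genes per direction with the smallest adjusted p of the additive fit; and a fixed set of 14 corticosteroid, natriuretic peptide, matrix and inflammatory genes with Nr3c2 and Myl2. The text gives fewer, by rank or where a further list names them. A few genes outside the rule are marked as such.

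The scripts were tested on simulated data for the CM-MRKO response, with 6830 genes and the spread of that pair of arrays. Of genes changed 1.5-fold, 54% passed the 1.5-fold threshold, as did 100% of those changed 2-fold and 1.06% of unchanged genes; because the spread came from the same pair, that last share says nothing about the real calls. The additive fit recovered 84% of genes changed 1.5-fold. All 4 simulated arrays had the spread of the CM-MRKO pair, whose log2 differences had an SD of 0.18. Real pairs with the WT vehicle array had SDs of 0.37 to 0.40, so the 84% does not carry over to the real fit. Of 100 lists of 12 unchanged genes 7 stood apart, and of 100 lists shifted by 0.2 on the log2 scale 86 did.

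Alternatives set beforehand were no background correction, an offset of 50, median scaling, cyclic loess, the deposited values on log2 without normalization, no filter, detection on every array, a detection limit of 0.05, the mean over detected probes, a 2-fold threshold and the mean of a list. Added after the data were seen were normexp with the receptor probes as negative controls, scaling to the median of detected probes, a requirement that a gene also differ from a further pool, and leaving out genes on which the WT vehicle array stood apart. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the remaining steps.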

Results

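Gene expression was measured in whole mouse hearts from a 2 by 2 design of genotype and treatment. Wild-type mice (WT) carried floxed alleles of the mineralocorticoid receptor gene Nr3c2, the nuclear receptor for aldosterone and deoxycorticosterone. CM-MRKO mice carried the same alleles with Cre recombinase driven from the ventricular myosin light chain locus, which removes the receptor from cardiomyocytes. After removal of 1 kidney, mice of 8 to 9 weeks received vehicle or deoxycorticosterone with salt (DOC/salt) for 8 days. RNA from 8 hearts was pooled for each of the 4 groups, and each pool was hybridised to 1 Illumina bead array. With 1 pool per group, no difference below has a replicate check, and no p-value across genes is given for the pairwise comparisons. A gene is called higher or lower where its normalized value differed by at least 1.5-fold.

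The 4 arrays differed in brightness. Median deposited intensities were 91.5 for WT vehicle, 92.6 for WT DOC/salt, 98.6 for CM-MRKO vehicle and 102.7 for CM-MRKO DOC/salt, and the 75th percentiles were 120.2, 147.6, 152.4 and 161.4. The number of detected genes was 5696, 6236, 6219 and 6534 in the same order. Over the 5471 genes detected on all 4 arrays, the WT vehicle array correlated with the others at Pearson r across genes of 0.975 to 0.978, and the other 3 arrays correlated with one another at 0.993 to 0.995. On the WT vehicle array 283 genes lay at least 1.5-fold below all 3 other arrays, against 8, 1 and 2 on the WT DOC/salt, CM-MRKO vehicle and CM-MRKO DOC/salt arrays.

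**Figure D1:**
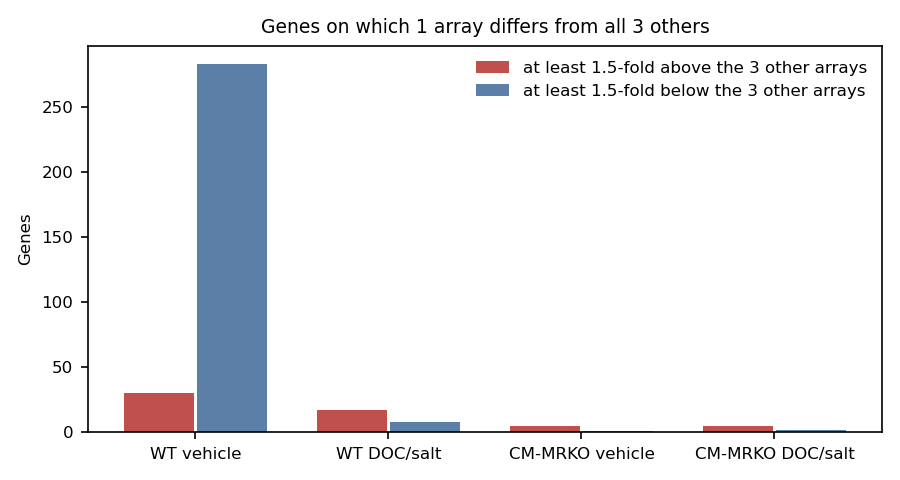
Number of genes (vertical axis) on which each array lay at least 1.5-fold above (red) or below (blue) all 3 other arrays, for the 4 arrays on the horizontal axis. The WT vehicle array has 283 genes below and 30 above, and the WT DOC/salt array has 17 above and 8 below.

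None of the probes carried the name Nr3c2 in the platform annotation, so the targeted gene was not analysed here and the genotype labels have no check of their own. Myl2, the ventricular myosin light chain whose locus drives Cre, had intensities of 17284 in WT vehicle, 15901 in WT DOC/salt, 19024 in CM-MRKO vehicle and 21083 in CM-MRKO DOC/salt. Nr3c1, which encodes the glucocorticoid receptor, was not detected on any array, and neither were Myh7, Col3a1 or Ccl2. Cd68 had no named probe.

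The first comparison asked what DOC/salt did in hearts without the cardiomyocyte receptor. In CM-MRKO hearts, the clock gene Per2 was 2.39-fold higher after DOC/salt (intensity 129.0 to 237.7) and Dbp, a clock output transcription factor, was 2.05-fold higher (588.3 to 1203). Hspa1a, an inducible heat shock protein, was 2.11-fold higher, although in WT it went the other way, from 191.3 to an undetected 108.5, and the glutathione transferase gene Gstt2 was 2.02-fold higher. The neutrophil genes S100a8, a calcium-binding alarmin, and Retnlg were 1.72-fold and 1.62-fold higher, and Col1a1, a chain of collagen type I, was 1.61-fold higher. Lower values were found for the interferon-induced gene Ifi35 (2.09-fold), the corepressor component Tbl1x (2.07-fold), Pcyt1a of phosphatidylcholine synthesis (1.72-fold), the translation repressor gene Eif4ebp2 (1.69-fold) and the transcription factor gene Scx (1.63-fold). Cacna2d1, a calcium channel subunit, and the kinase gene Pdpk1 were each 1.61-fold lower. On the deposited values Retnlg, Eif4ebp2, Scx, Cacna2d1 and Pdpk1 differed by less than 1.5-fold. So did Tbl1x (181.9 to 125.2) and Pcyt1a (157.5 to 122.6).

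Of the 11 circadian clock genes measured in CM-MRKO hearts, 3 were higher and 0 lower; Per2 and Dbp differed by 1.26 and 1.04 on the log2 scale, Ciart went from an undetected 105.6 to 139.4, and the list median of 0.33 exceeded those of all 10000 random lists. Neutrophil markers had a median of 0.47 (2 of 5 higher, percentile 100), with S100a8 at 0.78 and Retnlg at 0.70; the median was 0.21 with Ltf, detected on 1 array, set to its bound, and 0.14 with undetected members included. The heat shock list had a median of 0.17 (1 of 10 higher), with Hspa1a at 1.07 and Hsph1 at 0.54. Antioxidant genes had a median of 0.13 with 0 of 14 members past 1.5-fold, Txnip at 0.30 and Prdx1 at 0.22. The hypertrophy and fetal genes had a median of -0.14 with 0 of 9 past 1.5-fold, including Acta1 at -0.48 and Nppb at -0.14. Fibroblast markers had a median of -0.11 (2 of 14 lower), with Meox1 at -0.61 and Islr detected on the vehicle array alone. These were the 6 of 33 lists that stood in the lowest or highest 2.5% of random lists. The corticosteroid-responsive list had a median of 0.02 (percentile 60.4; 1 of 18 higher, Hif3a, undetected in vehicle), and its members Sgk1, Tsc22d3 and Per1 differed by -0.38, 0.08 and 0.15.

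In total 42 genes were higher and 28 lower among 6668 in the CM-MRKO response, and the balance turned to 14 higher and 21 lower among genes detected on both arrays. The technical spread, taken from pairs of probes of one gene, was 0.17 on the log2 scale. Only 8 genes passed without background correction, and 25 also differed the same way from the WT vehicle pool.

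The second comparison set the genotypes against each other under DOC/salt. In CM-MRKO hearts, Ppbp, a platelet chemokine, was 4.13-fold lower than in WT (307.8 in WT, 127.8 in CM-MRKO). A second detected Ppbp probe showed a smaller difference, 1.07 on the log2 scale for WT minus CM-MRKO (176.6 and 124.1). The platelet receptor gene Treml1 was 2.97-fold lower, and Itga2b, the platelet integrin chain, was 2.26-fold lower (187.4 in WT, 124.9 in CM-MRKO). Gp9, a subunit of the receptor for von Willebrand factor, read 227.8 in WT and an undetected 116.6 in CM-MRKO, and Mpig6b 180.7 and an undetected 120.3. No fixed list was made for platelet genes, although Ppbp and Pf4 belonged to the fixed blood marker list. Pf4, Itgb3 and Clec1b were not detected on any array. The interferon-inducible GTPase genes Irgm2 and Igtp were 2.46-fold and 2.35-fold lower, and Bst2, which encodes the virus-tethering protein tetherin, was 2.46-fold lower. Ifi35 was 1.97-fold lower after normalization but differed by less than 1.5-fold on the deposited values (242.7 in WT, 164.8 in CM-MRKO). S100a8 was 2.37-fold higher (660.9 in WT, 1578.5 in CM-MRKO), and Nppb, which encodes B-type natriuretic peptide, was higher by about 2-fold (intensities 5790 and 12170). Tnfrsf12a, the receptor of the cytokine TWEAK, was 1.98-fold higher, the cytokine gene Il15 1.80-fold higher and the elastin gene Eln 1.74-fold higher.

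The interferon response list was lower in CM-MRKO hearts under DOC/salt, with 7 of 13 members lower, 0 higher and a median of -0.60 (percentile 0). Bst2, Igtp, Ifit3 and Gbp3 differed by -1.30, -1.24, -0.92 and -0.82. Other detected probes showed smaller differences of the same direction. For WT minus CM-MRKO they were 0.30 and 0.48 for Ifit3 and 0.59 for Gbp3. Neutrophil markers were higher, with 4 of 5 past 1.5-fold and a median of 1.05 (percentile 100), among them S100a8 at 1.24 and S100a9 at 0.68. Retnlg (106.8 and 199.0) and Ltf (85.4 and 130.1) were under the detection limit in WT; the median was 0.68 with both set to their bounds and 0.11 with undetected members included. The extracellular matrix list had a median of 0.27 (percentile 100), with 20 of 23 members above 0 but 1 past 1.5-fold; Eln was at 0.80, Mfap4 at 0.57 and Col6a2 at 0.51. The hypertrophy and fetal genes had a median of 0.20 (1 of 9 higher), led by Nppb, with Nppa, the atrial natriuretic peptide gene, at 0.57. Atrial markers had a median of 0.48 (1 of 4 higher, Myl4 at 0.63), and ventricular markers had a median of 0.22 (0 of 4 higher, Myl3 at 0.28). Nppa belongs to both the hypertrophy and the atrial lists, so these 2 medians are not separate. Of the 4 atrial members 1 was detected on 1 array only, and the median was also 0.48 with it at its bound. Blood markers had a median of -0.29 (1 of 5 lower), with Ppbp at -2.05, Alas2 at -0.53 and the haemoglobin gene Hba-a1 at 0.12. These 7 lists were those that stood apart among 32.

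Under DOC/salt 59 genes were higher and 63 lower in CM-MRKO than in WT among 6689, and the technical spread was 0.19. Without background correction 26 genes passed, and 28 also differed the same way from the WT vehicle pool.

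**Figure D2:**
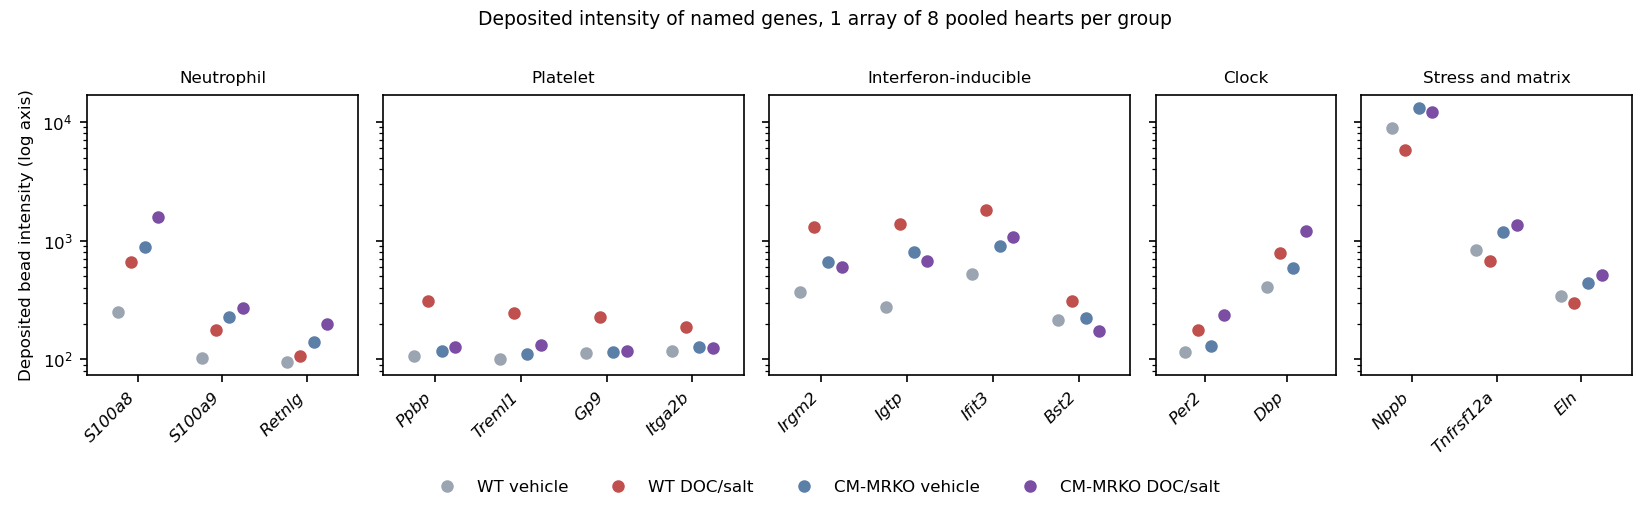
Deposited bead intensity (shared log axis) of 16 genes on each of the 4 arrays, 1 point per array of 8 pooled hearts, grouped by what the genes are known for. The 4 platelet genes drawn are brightest in WT DOC/salt (Ppbp 307.8), S100a8 is brightest in CM-MRKO DOC/salt (1578.5), and Nppb is dimmest in WT DOC/salt (5790).

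The third comparison asked what DOC/salt did in WT hearts. The interferon-inducible GTPase genes Igtp and Irgm1 differed by 1.91 and 1.63 on the log2 scale, and Ifit3 by 1.22, all higher after DOC/salt, and the interferon regulatory factor gene Irf7 went from an intensity of 110.1 to 200.6. S100a8 was higher by 0.94, and S100a9 went from an undetected 103.2 to 175.4. Hspa1a went from 191.3 to an undetected 108.5. Nppb was 2.08-fold lower (8913 to 5790), Tnfrsf12a about 2-fold lower (830.0 to 678.2) and Eln 1.92-fold lower (341.2 to 299.4) after normalization; on the deposited values Tnfrsf12a and Eln differed by less than 1.5-fold. Among genes detected on both arrays the highest ratios were those of Cd81, a tetraspanin, at 42.0-fold (138.5 to 5083), the mitochondrial acetyl-CoA synthetase gene Acss1 at 28.5-fold (148.3 to 3857), and Sod2, the mitochondrial superoxide dismutase gene, at 12.1-fold (264.3 to 3977). The protease gene Ctsb (9.39-fold), the proteoglycan gene Dcn (7.31-fold) and the myoglobin gene Mb (6.44-fold) followed the same pattern; on both CM-MRKO arrays these 6 genes lay close to the WT DOC/salt value.

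The interferon response list in WT hearts had 7 of 13 members higher, 0 lower and a median of 0.61 (percentile 100). Neutrophil markers had a median of 0.94 over 3 detected members (2 higher), which turned to -0.0217 with undetected members included. Blood markers had a median of 0.93 (3 of 5 higher), with Alas2 1.91-fold higher and Ppbp and Hbb-bt undetected in WT vehicle (106.6 to 307.8 and 103.5 to 184.8). The antigen presentation list had a median of 0.28 (3 of 10 higher), with B2m at 0.91, and a median of 0.14 with 2 members undetected in WT vehicle set to their bounds. The median of the extracellular matrix list was -0.23 (2 of 22 lower) but 0.29 with median scaling and 0.35 on the deposited values. Immediate early genes had a median of -0.49 (2 of 10 lower), which was 0.02 with median scaling and 0.13 on the deposited values. The oxidative phosphorylation list had a median of 0.20 (4 of 25 higher), with Uqcrb at 2.70, and -0.17 when arrays were scaled to their detected probes. Its 4 higher members, Uqcrb, Atp5a1, Cox5a and Ndufs3, were low on the WT vehicle array alone, and the same 4 were higher in CM-MRKO vehicle than in WT vehicle. Alas2, B2m, Igtp and Irgm1 were likewise dimmest on the WT vehicle array. Atrial markers had a median of -0.55 (2 of 4 lower), with Myl4 at -0.77, and 0.01 on the deposited values. These 8 lists stood apart among 33. The circadian clock list had a median of 0.26 (percentile 96.9), with Per2 at 0.56 and Dbp at 0.36, and the corticosteroid-responsive list was at percentile 27.3 (1 of 17 higher, 1 lower). Its largest differences were in Fkbp5 (120.9 to an undetected 109.2) and Hif3a (an undetected 95.1 to 126.2), with Sgk1 at -0.06, Tsc22d3 at 0.47 and Per1 at 0.01.

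In WT hearts 562 genes were higher and 261 lower among 6391, with a technical spread of 0.33. Only 57 of these 823 also differed the same way from the CM-MRKO vehicle pool, and 313 of them are the genes on which the WT vehicle array stood apart, which are calls in this comparison by construction; on the deposited values without normalization 1719 were higher and 2 lower.

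The fourth comparison set CM-MRKO vehicle against WT vehicle. The neutrophil genes S100a8, S100a9 and Retnlg were higher in CM-MRKO, with S100a8 2.64-fold higher, S100a9 at 103.2 in WT and 226.0 in CM-MRKO, and Retnlg at 94.3 and 139.1, where the WT values of S100a9 and Retnlg were undetected. Of 4 neutrophil markers 3 were higher, and the list median of 1.14 (percentile 100) was 0.70 with members detected on 1 array set to their bounds and turned to -0.0454 with undetected members included. Blood markers had a median of 0.59 (2 of 4 higher), with Alas2 at 0.86 on the log2 scale and Hbb-bt undetected in WT. Immediate early genes had a median of -0.29 (1 of 10 lower), with Klf4, a transcription factor gene, at -0.66; the list was at 0.14 with median scaling and 0.25 on the deposited values, where Klf4 was at 0.03. These were the 3 of 33 lists that stood apart. Hspa1a was 2.75-fold lower (191.3 in WT, 139.4 in CM-MRKO) and Cavin1, a caveolar coat gene, 2.19-fold lower (143.1 and 120.9) after normalization, but both differed by less than 1.5-fold on the deposited values. In CM-MRKO Cd81 was 33.1-fold, Acss1 23.6-fold and Sod2 10.5-fold higher, all 3 dim on the WT vehicle array alone. Nppb differed by 0.09 and Nppa by 0.19.

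In the vehicle pools 474 genes were higher and 165 lower in CM-MRKO among 6364, with a technical spread of 0.33. Of these 639 genes, 17 also differed the same way from the WT DOC/salt pool, and 313 are again the genes on which the WT vehicle array stood apart, by construction; on the deposited values 1886 were higher and 0 lower.

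The difference of the DOC/salt responses, CM-MRKO minus WT, addressed what the cardiomyocyte receptor does to the response. The interferon response list was lower in this difference, with 8 of 13 members lower and a median of -0.63 (percentile 0), led by Igtp at -2.28 and Irgm1 at -1.88. Igtp and Irgm1 were also dimmest on the WT vehicle array (276.3 against 668.4 to 1380.5, and 334.0 against 974.5 to 1443), and between the DOC/salt pools alone they differed by -1.24 and -0.72, with a list median of -0.60. Blood markers had a median of -1.37 (3 of 5 lower), with Alas2 at -1.39, and the antigen presentation list had a median of -0.30 (3 of 10 lower), with B2m at -0.87. The WT vehicle array was the dimmest of the 4 for Alas2 (375.5 against 792.0 to 1039) and B2m (2161 against 4822 to 5903); between the DOC/salt pools alone the blood median was -0.29 (1 of 5 lower) and the antigen presentation median 0.05 (0 of 10 lower). Atrial markers had a median of 0.58 (2 of 4 higher; Myl4 at 0.85) and ventricular markers of 0.39 (1 of 4 higher; Irx4 at 0.70). The extracellular matrix list had a median of 0.32 (3 of 23 higher), with Eln at 1.10 and Col1a1 at 0.69, and its median turned to -0.17 with median scaling and -0.16 on the deposited values. Immediate early genes had a median of 0.42 (3 of 10 higher, 1 lower) that turned to -0.03 and -0.05 under the same settings, and oxidative phosphorylation a median of -0.28 (4 of 25 lower, 1 higher) that turned to 0.05 with scaling to detected probes. Single genes included Ppp2r5b at 1.33, Pkd1 at 1.23, Tada3 at 1.21 and Tnfrsf12a at 1.12; on the deposited values these 4 and Eln were at less than 1.5-fold.

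Across 6830 genes, 464 were higher and 690 lower in the difference of responses, with a technical spread of 0.37. The balance turned with scaling, to 835 higher and 456 lower with scaling to detected probes, and was 69 and 1983 with median scaling. It was 439 and 425 without the genes on which the WT vehicle array stood apart, a choice of genes that itself follows from their change. Of these 1154 genes, 78 also differed the same way between the DOC/salt pools of the 2 genotypes, which do not involve the WT vehicle array. That pair of pools is itself part of the difference of responses, so some of this agreement is built in.

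**Figure D3:**
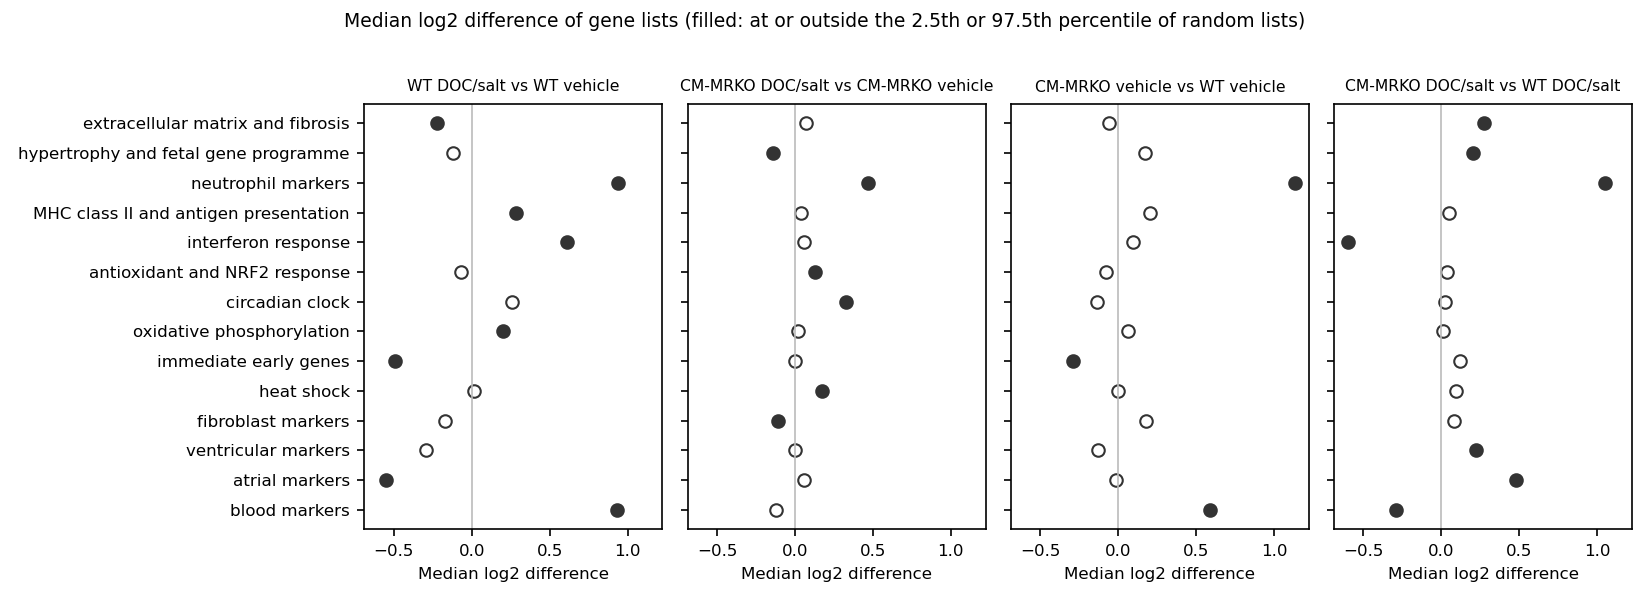
Median log2 difference (horizontal axes) of the 14 gene lists (vertical axis) that stood apart in at least 1 of the 4 pairwise comparisons; filled points stand in the lowest or highest 2.5% of random lists. The interferon list lies at 0.61 in the WT response and -0.60 in the genotype difference under DOC/salt; in the WT response the extracellular matrix, immediate early, atrial and oxidative phosphorylation medians, and in the vehicle pools the immediate early median, change sign under other scalings, and the neutrophil medians of the WT response and the vehicle pools change sign with undetected members included.

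The 2 responses share no array, so their overlap compares separate pools. In both genotypes 5 genes were higher after DOC/salt, against 1.97 given by independent lists, and 3 were lower, against 0.841, while 5 changed in opposite directions, against 2.76. The 5 were S100a8, Hif3a, Cyp2b10, Qtrt1 and Sppl2c, and the 3 were Meox1, Scx and the histone gene H2ac12. They are named because the count is small. In WT the 3 were called lower only after normalization. Deposited WT intensities, vehicle then DOC/salt, were 338.5 and 328 for Meox1, 142 and 139.7 for Scx, 294.6 and 297.7 for H2ac12. Hif3a, Cyp2b10, Qtrt1 and Sppl2c were detected only on the DOC/salt arrays. The genotype difference was the same under both treatments for 4 genes that were higher in CM-MRKO, against 3.16 given by independent lists, and for 8 that were lower, against 1.06, while 10 differed in opposite directions, against 4.31. The 4 were S100a8, S100a9, Retnlg and Golga4, and the 8 included Bst2, the elongation factor gene Eef2 and Gsn, which encodes gelsolin. The lower calls in the vehicle pools arose only with normalization, since 0 genes were lower there on the deposited values. Deposited vehicle intensities in WT and CM-MRKO were 215.1 and 221.7 for Bst2, 707.8 and 749.9 for Eef2, 499.7 and 546.6 for Gsn. Across the 5471 genes detected on all arrays, the 2 responses correlated at Pearson r of -0.01 and Spearman rho of -0.01, and the 2 genotype differences at -0.09 and -0.08. These correlations run across genes, which are not independent replicates. The 2 brightest detected probes of a gene correlated at only 0.24 in the WT response and 0.15 in the CM-MRKO response. For the genotype differences they correlated at 0.17 under vehicle and 0.28 under DOC/salt. Values near 0 between responses therefore cannot show that the responses are unrelated.

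The additive fit asked which changes were common to both genotypes or both treatments. S100a8 had the smallest adjusted p for genotype: it was 1.32 higher in CM-MRKO on the log2 scale (SE 0.19, adjusted p = 0.16 by limma) and higher in both pairs of pools. Retnlg and S100a9, undetected on both WT arrays and on WT vehicle respectively, followed, and Bst2 at -0.98 led the lower genes. In the vehicle pools the deposited intensity of Bst2 was not lower in CM-MRKO (215.1 in WT, 221.7 in CM-MRKO). For treatment the fit ranked S100a8 at 0.86 and Per2 at 0.91 among the first genes. With limma 0 of 6830 genes had an adjusted p under 0.05 for treatment (287 at an unadjusted p under 0.05) and 0 for genotype (267), where chance would give 342 at the unadjusted threshold. These counts depend on the processing: S100a8 alone passed for genotype with no background correction, an offset of 50, the deposited values or detection on every array. For treatment and genotype, 33 and 24 genes passed with median scaling, 29 and 30 with scaling to detected probes and 15 and 21 with no filter, and 0 and 0 with the other 4 settings. With either scaling Cd81, Acss1, Sod2 and Idh2 passed for both effects. These genes were dim on the WT vehicle array alone (Cd81 138.5 against 4116.8 to 5083.1). Their passes rest on that array and show no change common to both genotypes or both treatments. The fit takes the interaction as its residual, with 1 degree of freedom.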

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

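All tests in this part were chosen after the results were seen, except the count after cyclic loess, which was set out before it was run. DOC/salt moved 4 genes detected on all arrays by at least 1.5-fold in opposite directions in the 2 genotypes; these differences were not tested. The log2 difference of responses, CM-MRKO minus WT, was -1.24 for the drug transporter gene Abcb1b (0.63 in WT, -0.60 in CM-MRKO) and -1.30 for G3bp2 (0.59 and -0.70), a stress granule gene. It was 1.23 for Pkd1 (-0.64 and 0.59) and 1.33 for the phosphatase subunit gene Ppp2r5b (-0.66 and 0.67). Deposited intensities differed little between WT vehicle and WT DOC/salt for Pkd1 (144.6 and 142.0) and Ppp2r5b (125.9 and 119.9). G3bp2 (378.5 against 720.6 to 1060.2) and Abcb1b (112.0 against 156.7 to 193.9) were dimmest on the WT vehicle array, so their higher values in WT rest on that array. Hspa1a, which also went opposite ways, was undetected in WT DOC/salt and is not among the 4. Signal also appeared in probes outside the comparisons: 394 probes without a gene name were detected on all 4 arrays. Of these, 40 (10.2%) differed by at least 1.5-fold in the WT response and 3 (0.76%) in the CM-MRKO response. Named genes detected on both arrays changed at similar shares, 533 of 5541 and 35 of 6085, so the unnamed probes do not stand out.

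The WT vehicle array lay at least 2-fold below all 3 other arrays for 83 genes, among them Cd81, Acss1 and Sod2. Cyclic loess, which removes differences that follow intensity, left 75 genes in that state. The genes had been picked after quantile normalization, which already removes most such differences. The count therefore cannot decide whether uneven brightness contributed. At the level of probes, 112 were lost in this way, and 61 pairs could be formed with another detected probe of the same gene; the other probes had a median deficit of -0.12 (quartiles -0.59 and 0.23) beside -1.61 for the lost ones, which argues against fewer transcripts as the cause for these genes as a set. In the same 61 pairs, 86.9% of the other probes were less than 2-fold below and 8 were at least 2-fold below. This share restates the median deficit and is no second test. As an example, an Atp2a2 probe read 222.0 against 5402 to 6466 elsewhere while the gene's other probe read 15158 against 19264 to 21344. A candidate explanation is therefore probe-level loss on this array, but for 4 of the 40 genes in these pairs (Dcn, Lamp2, Trip12 and Eef1b2, the last 3 named after their values were seen) another probe was at least 2-fold below too, genes with 1 probe cannot be checked, and why probes were lost stays open.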

How the results depend on the processing

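Counts are given in the order WT response, CM-MRKO response, vehicle genotype difference, DOC/salt genotype difference and difference of responses, and were 823, 70, 639, 122 and 1154 as reported; genes changed the same way were 8 by treatment and 12 by genotype. The cause of the changes was not tested unless a setting's construction gives it. No paired analysis was possible because each group is 1 pool, and leaving out an array leaves the additive fit with no residual. Signal over background limits genes near the detection limit. No background correction gave 277, 8, 209, 26 and 403 genes, 1 and 1 shared, and 1 gene for genotype in the additive fit (S100a8); an offset of 50 gave 398, 14, 295, 32 and 598, 1 and 1 shared, and 1 for genotype. Both compress ratios of dim genes. Median scaling gave 1954, 1738 and 2052 for the comparisons with the WT vehicle array, and 33 genes for treatment and 24 for genotype in the additive fit, led by Cd81 and Acss1; it moved the median of all genes to 0.39, 0.37 and -0.36 in those comparisons. List medians that turned were the extracellular matrix (0.29) and immediate early genes (0.0204) in the WT response, immediate early genes in the vehicle pools (0.14), and both lists in the difference of responses (-0.17 and -0.0349). The deposited values on log2 gave 1721, 8, 1886 and 39 for the 4 pairwise comparisons, 4 shared by treatment, 1 additive gene for genotype (S100a8), and a correlation of the genotype differences of -0.12 in place of -0.09; medians of all genes were 0.39, 0.44, 0.13 and -0.29 in the WT response, vehicle pools, DOC/salt pools and difference of responses. There Zfp36 (0.0541) and the atrial (0.00601), matrix (0.35) and immediate early (0.13) lists turned in the WT response, Klf4 (0.0335) and immediate early genes (0.25) in the vehicle pools, and the matrix (-0.16) and immediate early lists (-0.0549) in the difference of responses. No filter gave 1430, 357, 1246, 407 and 2624 of more genes tested, 18 and 22 shared, 15 and 21 additive genes and a correlation of -0.0386, and neutrophil markers, with undetected members included, were at -0.0217 in the WT response and -0.0454 in the vehicle pools. Detection on every array, which tests fewer genes, gave 533, 35, 393, 71 and 738, 4 shared by treatment and 1 additive gene for genotype (S100a8). A detection limit of 0.05 gave 125 for the CM-MRKO response. The 2-fold threshold gave 147, 7, 136, 15 and 230, with 0 and 1 shared. Of the settings added after the data were seen, receptor probes as negative controls gave 167 for the CM-MRKO response, 221 for the DOC/salt genotype difference, and 21 and 21 shared. Scaling to detected probes gave 4 shared by treatment, 29 and 30 additive genes, and oxidative phosphorylation medians of -0.17 in the WT response and 0.0508 in the difference of responses, with medians of all genes of -0.13, -0.12 and 0.14 where the WT vehicle array enters. Requiring a further pool gave 57, 25, 17, 28 and 78. Each such requirement reuses an array of its own comparison, so some agreement is built in. Leaving out genes on which the WT vehicle array stood apart gave 510 for the WT response and 326 for the vehicle pools. All 313 such genes are calls in these comparisons by construction, so leaving them out tests nothing there. The share of higher calls, 68.3%, 60%, 74.2%, 48.4% and 40.2% as reported, moved with scaling and with other settings. Scaling took it to 99.5%, 70.7%, 99.7% and 3.36% with median scaling (all but the DOC/salt genotype difference), to 99.9%, 87.5%, 100%, 71.8% and 0.145% on the deposited values, to 78.7% and 86.1% with cyclic loess in the WT response and vehicle pools, and to 44.2%, 47.7% and 64.7% with scaling to detected probes where the WT vehicle array enters. No background correction gave 85.9%, 94.7%, 34.6% and 24.6% (all but the CM-MRKO response), an offset of 50 gave 79.1%, 89.8% and 37.5% for the WT response, vehicle pools and DOC/salt pools, and the 2-fold threshold gave 95.9%, 71.4%, 98.5%, 33.3% and 16.5%. Detection on every array gave 40% for the CM-MRKO response (14 higher, 21 lower), and no filter gave 49.6% there (177 and 180) and 61.1% in the vehicle pools. Without genes on which the WT vehicle array stood apart, a choice that follows from the calls, it was 54.7%, 58.6% and 50.8% in the WT response, vehicle pools and difference of responses, and 72% in the CM-MRKO response where a further pool was required. Of 382 alternative list medians 322 kept their direction and stood apart, 45 kept only their direction and 15 turned; of 2651 alternative values of named genes 2401 kept their side of 1.5-fold, 203 fell short of it, 45 newly passed and 2 turned. In the genotype difference under DOC/salt 80 of 84 list values and 470 of 495 gene values were kept, and none turned. Both counts of gene values include no filter, detection on every array and a detection limit of 0.05. Those settings change only which genes are counted, so all 241 gene values were kept under each by construction, which tests nothing.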

Other observations

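All tests in this part were chosen after the results were seen. Of 17 genes that lay at least 1.5-fold above all 3 other arrays in the WT DOC/salt pool, 6 were platelet genes and 4 belonged to the interferon response list. Array spread resampled from the CM-MRKO pair gave 4.70 such genes in all. That pair had an SD of log2 differences of 0.18, against 0.20 and 0.21 for WT DOC/salt with the CM-MRKO arrays, so 4.70 may be too low. It holds no spread between pools of the same group. Gp1bb, which encodes a platelet glycoprotein subunit and falls outside the rule for named genes, read 143.5 in that pool and 89.7, 104.7 and 113.6 in WT vehicle, CM-MRKO vehicle and CM-MRKO DOC/salt. The interferon regulatory factor gene Irf9, also outside the rule, read 344.7 against 177.7, 245.3 and 268.8. Apod, a lipid carrier gene, read 572.2 against 217.9, 242.3 and 334.7. The 8 genes below all 3 others in that pool included Nppb, Tnfrsf12a, Eln, Adamtsl2 and, outside the rule, Mtor and Tubb2b. Of those named, all but Nppb differed from WT vehicle by less than 1.5-fold on the deposited values. Deposited intensities in WT vehicle and WT DOC/salt were 722.5 and 723.6 for Tubb2b, 208.0 and 192.8 for Mtor, and 172.5 and 148.9 for Adamtsl2.

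More blood left in the WT DOC/salt hearts was weighed as a source of the platelet signal. Of 10 platelet genes, looked at because of this pattern, 7 were detected on the WT DOC/salt array and at least 1.5-fold higher there than in CM-MRKO DOC/salt on the normalized values; Itgb3 (-0.13 on the log2 scale) and Clec1b (0.29) were detected on no array, as was Pf4, so the count is no test of platelet genes as a class. The red cell and neutrophil transcripts Hba-a1, Hbb-bt, Slc4a1, Alas2, S100a8 and S100a9 had a median of -0.0549 in the same contrast, but the members went both ways and decide nothing: Alas2 (0.53) and Hbb-bt (0.29) were higher in WT, S100a8 (-1.24) and S100a9 (-0.68) in CM-MRKO, as under vehicle, and Hba-a1 lay near the top of the scale on all arrays, so more blood cannot be told apart from a change in the hearts. Other detected probes of the platelet and interferon genes had a median of 0.53, but only 4 such probes of 3 genes exist, so gain of signal at single probes cannot be told apart from a change in transcripts. A platelet or interferon response of the WT hearts to DOC/salt, or of a few animals in the pool, may also account for it, and neither was tested.

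The clock genes Per2 and Dbp were higher after DOC/salt in CM-MRKO hearts, with smaller differences of the same sign in WT hearts. A different time of day at collection is a candidate explanation, in which case genes of the opposite phase would be lower; the 2 that were measured, Clock and Nfil3, had a median of -0.13, too few to decide, and collection times are not given in the labels. A general corticosteroid response might also account for it, but the corticosteroid-responsive list without Per1 stood at percentile 17.3 in CM-MRKO and 22.5 in WT, where members of both signs decide nothing. Time of day and treatment cannot be told apart with these pools.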
